A study of Mus musculus with 12 samples.

How the data were processed

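Microglia were isolated from the corpus callosum of C57BL/6 mice by magnetic sorting of CD11b-positive cells, and each sequenced sample pooled 2 mice, per the labels. Polyadenylated RNA was sequenced as paired-end reads. The 12 libraries fall into 3 groups taken from the sample titles: 4 Control libraries, 5 Vehicle libraries from mice that received cuprizone for 10 weeks, then 2 weeks of recovery with 0.1% bovine serum albumin in saline, and 3 Nrg1 libraries from mice on the same schedule that received neuregulin-1 beta 1. The dose is 30 µg/kg/day in the series description, and the sample labels print the same number with the unit g. Trimmomatic and mm10 are named in the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here.

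The deposited table holds log2 values of scaled CPM, reads per gene relative to library depth, with 4 added, as read from the values: the lowest value is 2 and no header states the formula. The table lists 27102 rows, with columns for a symbol, an Ensembl number and an Entrez gene number, and 3366 rows with values carry only a number as label. Of these, 23233 rows had values in all 12 libraries and 3869 had none in any. Subtracting 4 after back-transformation gave whole multiples of 1 step per library. With a tolerance of 0.01 reads, 100% of the values were whole in each library, so the read total of each library over the listed rows was recovered by dividing by the step. The back-transformed columns summed to between 465491 and 1497645 CPM, so a scaling factor per library is part of the deposited values. Since the unit is a log2 scale, no count model was run, although the design fixed beforehand had assumed a table of counts. The fallback written in that design was used in its place.

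Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, all 12 libraries in 1 model of group means, and Benjamini-Hochberg adjustment at 0.05. The 16925 rows at 1 CPM or more in at least 3 libraries were tested. Fold changes are on the log2(CPM + 1) scale, which understates changes of low rows. The 33 gene lists fixed beforehand hold 594 genes, and were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. For comparisons sharing a group, 100 simulations of unchanged groups were run over all libraries. The same was done, chosen after the data were seen, over the 9 with the fewest reads. Each row had its residual spread, the same in every group, and rows were drawn independently. Read counts differed more between Control replicates 1 and 2 than between any Vehicle pair. The simulated values are thus a reference under equal spread, and may differ from the values these libraries would give with no effect. A list needed 3 tested members, which left 31. Rows are named by the rule fixed beforehand: for each comparison the 8 largest rises and falls past the threshold with a mean of at least 5 CPM in the higher group and no overlap of libraries, without predicted genes, or, where nothing passed, the 5 rows with the smallest p in each direction as values only. Labels that are only a number were skipped as well. The rule also names up to 4 members of each list, or 2 by p where none passed, and a fixed set of 22 genes. Row labels did not carry the levels of the genes they name, so list members are given as counts per list and the 22 genes as levels, without fold changes. Rows are called by their labels throughout. Where the function of a gene is given, it is background on the gene the label names and is not read from the values of the row.

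Chromosomes of the labels were looked up by Entrez number in the RefSeq table of GRCm38.p6. A number was found for 21598 of the 23233 rows, and for 19863 of those that carry a symbol, 99.0% had the symbol or a synonym of it in that table. Symbols and numbers of these rows thus name the same gene.

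The test was tried on simulated counts with the libraries' own depths, a dispersion of 0.0683 estimated from the Vehicle libraries, no difference between libraries of high and low depth, and 200 changed rows. For Vehicle against Control with 12 libraries and 16058 rows, 17 of 67 rows changed 2-fold, 55 of 67 changed 4-fold and 60 of 66 changed 8-fold were recovered. Of the 140 rows called, 8 were unchanged. With the 9 libraries of fewest reads and 15925 rows, the numbers were 6 of 67, 39 of 67 and 57 of 66, with 12 unchanged rows among 114 called. That share lies above the nominal 0.05, so calls within these 9 libraries may hold more false ones than the adjustment allows. The real libraries did differ between high and low depth, so recovery in them may be lower. A list raised 2-fold, the lysosome list, was called in each of the 3 simulated comparisons. In Nrg1 against Vehicle with 12 libraries 1 other list was called too. Some lists share members with the lysosome list, so this other list may have been raised in part.

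The depth sets the floor. A count of 0 allows up to 3 reads, which is 3.47 to 6.19 CPM in the 9 libraries with the fewest reads, called shallow, and 0.296 to 0.773 CPM in the other 3. Intervals and floors cover counting error only. No pair of libraries of a group agreed within sampling noise: over rows with 20 or more reads in the pair, the lowest chi-square per degree of freedom was 3.05, between Nrg1 replicates 2 and 3. Alternatives chosen before the data were examined were quantile normalization, no filter, a filter of 5 CPM, a pseudocount of 0.1, voom with sample quality weights on the recovered reads, a fit of only the groups compared, an effect-size threshold, the replicate number as a term, the oligodendrocyte marker rows as a covariate, and leaving out each library. After the data were seen, 6 were added: a pseudocount of 4, rescaling each library to the same sum of CPM, the 9 shallow libraries alone, depth class as a covariate, Nrg1 replicate 1 moved by 1 row, and these last settings together. Moving by 1 row left out rows whose label has no chromosome.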

Results

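The transcriptome of CD11b-sorted microglia from the corpus callosum was measured in mice fed a control diet or recovering from cuprizone, a copper chelator that causes loss of myelin. The 4 Control, 5 Vehicle and 3 Nrg1 libraries each pooled 2 mice. Recovered reads over the listed rows ranged from 596857 in Vehicle replicate 5 to 5808854 in Nrg1 replicate 1. Of the 12 libraries, 9 held 596857 to 753362 reads. Control replicates 3 and 4 held 4828938 and 4388929 reads, and together with Nrg1 replicate 1 they form a second class. These 3 are called deep and the other 9 shallow, a split that crosses the Control and Nrg1 groups and leaves no deep library in the Vehicle group. Between 12684 and 14202 rows had at least 1 read in the shallow libraries, and 18565 to 22035 in the deep ones.

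**Figure D1:**
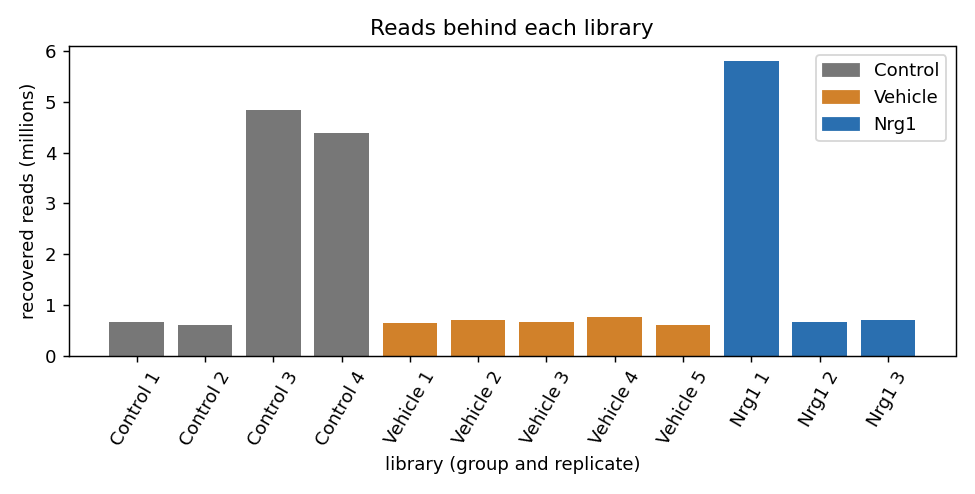
Bars give the recovered reads of each library, coloured by group. Control replicates 3 and 4 and Nrg1 replicate 1 hold 4388929 to 5808854 reads, and the other 9 libraries hold 753362 or fewer.

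The row labels were first compared with genes that CD11b-sorted cells express, most of them at a high level. Itgam encodes CD11b, the protein used for the sort. The row labelled Itgam held 0 reads in 10 of 12 libraries, 1 read in Control replicate 4 and 195 reads in Nrg1 replicate 1. The row labelled Actb, for beta-actin, held 0 reads in 10 libraries, and the rows labelled Eef1a1, Tmsb4x and mt-Co1 also held 0 reads in 10 each. The row labelled mt-Co2 held 0 reads in 11. The row labelled Gapdh stood at 3.06 CPM in Control replicate 3. In both deep Control libraries all 7 of these rows lay under 10 CPM. The row with the most reads in 8 of the 9 shallow libraries carried the label Usp46, a deubiquitinase. It took 15.9% of the reads of Control replicate 2 (95% exact binomial interval 15.8 to 16.0) and 3.13% to 6.37% in the other shallow libraries. In the deep libraries it took 0.0272% or less.

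Marker lists gave the same picture. The median percentile of 31 ribosomal protein labels among all rows with values was 55.7 over the libraries, where 50 is the middle. It was 33.99 for 14 homeostatic microglia labels and 69.3 for 23 labels of disease-associated microglia, the set of genes that rises in microglia around damage. It was 55.3 for 11 oligodendrocyte labels and 19.8 for 8 mitochondrially encoded genes. Over the 32 lists with at least 5 rows, these medians ran from 19.8 to 70.5. Of the 22 genes fixed beforehand, 18 had a row with values, and Nrg1, Tmem119, Spp1 and Mki67 were listed without values. The row labelled P2ry12 reached at most 2 reads in any shallow library, and the row labelled Apoe at most 6. The row labelled Trem2 had 6 to 25 reads in the shallow libraries and that labelled Itgax 64 to 225. The rows labelled Il1b, Clec7a and Egfr held 0 reads in every shallow library. Among ErbB receptors, the targets of neuregulin-1, the row labelled Erbb3 had 3091 reads in Control replicate 3 and 7 to 28 in the shallow libraries, and the row labelled Erbb2 had 304 reads and 4 to 11. These are levels of rows, and they are not read here as levels of the genes named.

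The share of rows at 1 CPM or more depended on the chromosome of the label. In Control replicate 3 it was 80.5% over 11597 labels on chromosomes 1 and 10 to 19 and 18.4% over 1524 labels on chromosomes 8 and 9. Between these it was 58.7% on chromosome 2, 53.7% on chromosome 4 and 42.8% on chromosome 6. Vehicle replicate 2 gave 76.2% for chromosomes 1 and 10 to 19 and 23.2% for chromosomes 8 and 9. On chromosomes 1 and 10 to 19, labels of olfactory and vomeronasal receptors, which serve in the nose, were at 1 CPM in 77.6% of 477 rows in Control replicate 3, against 80.6% of the other 11120. Every listed row with a label on chromosome 1 had values, while 53.2% of those on chromosome 5 and 56.0% of those on chromosome X did.

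**Figure D2:**
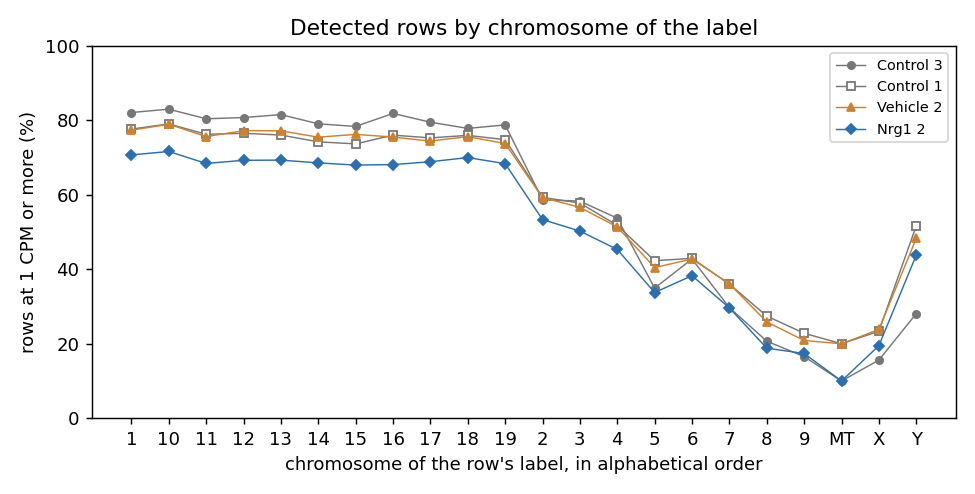
Points give the percentage of rows at 1 CPM or more for each chromosome of the row labels, in alphabetical order, in 4 libraries. The share is 82.1% on chromosome 1 and 16.6% on chromosome 9 in Control replicate 3.

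Libraries were compared by Spearman correlation across rows, which are not independent replicates. Pairs of shallow libraries gave rho of 0.79 to 0.895, and Control replicates 3 and 4 gave 0.97. A deep Control library and a shallow library gave 0.668 to 0.725, whatever the group of the shallow one. Nrg1 replicate 1 gave 0.192 to 0.267 with the 11 other libraries. When its values were moved by 1 row along the order of the labels on the genome, rho with Control replicate 3 went from 0.256 to 0.903, and rho with Vehicle replicate 2 from 0.201 to 0.685. No other move of up to 5 rows gave more than 0.286 with any library. Each of the 11 other libraries agreed best with the rest at its deposited place. All comparisons below use the values as deposited unless Nrg1 replicate 1 is said to be moved.

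**Figure D3:**
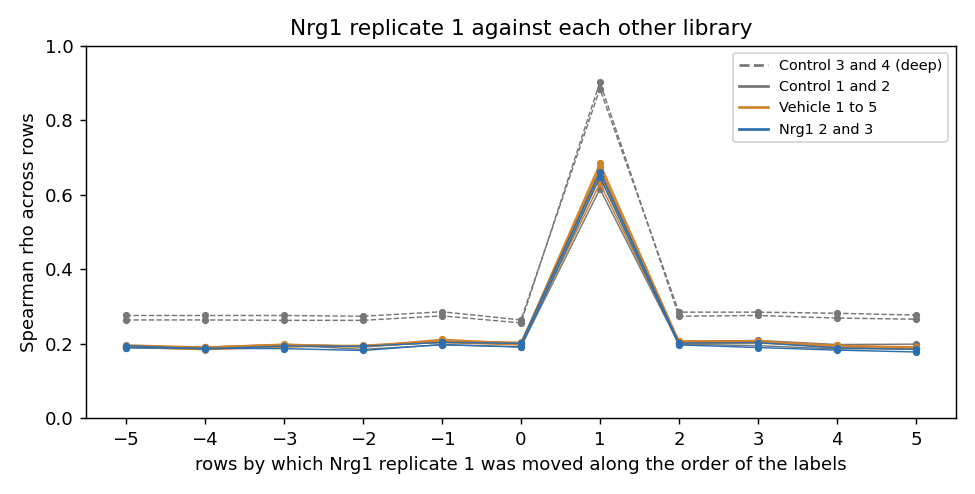
Each line gives the Spearman rho across rows between Nrg1 replicate 1 and another library after moving Nrg1 replicate 1 by -5 to 5 rows. All lines rise at a move of 1 row, to 0.903 and 0.885 for the deep Control libraries and to between 0.616 and 0.685 for the shallow ones.

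Vehicle against Control asks how microglia of mice 2 weeks after cuprizone differ from those of control mice. No vehicle is recorded for the Control mice, so the diet and the vehicle given cannot be told apart here. One row passed, higher in Vehicle. It is labelled Zfp114 (ENSMUSG00000068962), with 166 ± 84.3 CPM in Vehicle (SD, n = 5) and 2.55 ± 3.96 in Control (SD, n = 4). Every Vehicle library had 84 to 200 reads on it, and the Control libraries 0 to 10. The difference was 5.98 ± 0.73 on the log2 scale (standard error, limma adjusted p = 0.00528), and the libraries did not overlap. At an unadjusted p under 0.05 there were 1759 rows, against 846 expected by chance. This excess was lost without either deep Control library, with 545 rows against 834 expected without Control replicate 3 and 546 against 819 without Control replicate 4. There were 3090 against 837 without Control replicate 1, 2989 against 841 without Control replicate 2 and 3765 against 818 without Nrg1 replicate 1. With the oligodendrocyte marker rows as a covariate 3254 rows passed, 1560 higher and 1694 lower. These labels did not carry the levels of their genes. The median percentile of the 11 rows with values was 42.2 and 36.4 in Control replicates 3 and 4 and 23.2 in Nrg1 replicate 1 as deposited. It was 50.2 to 74.9 in the shallow libraries. The covariate itself was the mean log2 value of the tested marker rows, which these percentiles describe only in part. Depth class as a covariate gave 2 rows, so depth class alone does not account for the 3254 rows. Their cause was not tested, and they are not read as an effect of cuprizone. The count of rows past the threshold was 0 without Control replicate 2 and 14 without Nrg1 replicate 1. Without Control replicate 2 the adjusted p of the row labelled Zfp114 was 0.0503 with limma (0.00031 to 0.0503 over the libraries left out). Within the shallow libraries, 5 Vehicle against 2 Control, 64 rows passed, 40 higher and 24 lower. Among them was the row labelled Zfp114 at 5.62 ± 0.58 (adjusted p = 4.12e-05 with limma). The spread in that fit came mostly from the Vehicle libraries, whose read counts differed less than those of Control replicates 1 and 2. The p-values may thus understate the spread of the Control libraries. The deep libraries hold no Vehicle library, so no second value can be given. On the row labelled Zfp114 the deep Nrg1 library stood at 10.1 CPM as deposited and 3.35 moved. The shallow Nrg1 libraries stood at 52.8 and 61.7 CPM. Part of the difference over all 12 libraries may thus reflect depth class.

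By the naming rule applied to the shallow libraries, which was chosen after these values were seen, the largest rises included the row labelled Pitpnm2os1, at 161 ± 72.8 CPM in Vehicle (SD, n = 5) and 7.503 ± 4.78 in Control (SD, n = 2), and the row labelled Nadsyn1, at 32.3 ± 9.50 and 2.24 ± 0.25. Both deep Control libraries, replicates 3 and 4, lay below every Vehicle library on 5 of the 8 rises named by the rule, those labelled Zfp114, L3mbtl3, Pitpnm2os1, Olfr1184 and Nadsyn1. They did not on the other 3: they stood at 43.9 and 47.2 CPM on the row labelled Kynu, 56.3 and 26.6 on that labelled Prkch and 24.3 and 23.1 on that labelled Btbd19, against Vehicle means of 29.9 ± 17.7, 22.2 ± 11.8 and 28.2 ± 13.4 CPM (SD, n = 5). The largest falls were in rows labelled Myh11, Dpcd and Ms4a18, where the spread between the 2 Control libraries exceeded their mean. The row labelled Dpcd had 95.9 ± 51.4 CPM in Vehicle and 3532 ± 4538 in Control. Both deep Control libraries lay above every Vehicle library on 6 of the 8 falls named by the rule, among them the row labelled Dpcd at 1252 and 3018 CPM. They did not on the rows labelled Sertad4 and Ms4a18, and on the last they stood at 0.887 and 1.80 CPM, below every Vehicle library. Deep libraries differed from shallow ones whatever the group, and no share over all rows was computed. The place of the deep Control libraries may thus reflect depth class, and these counts are not read as a second test.

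Nrg1 against Vehicle is the comparison in which the diet is matched, and asks what neuregulin changed. With limma, 0 of 16925 rows passed, and 1248 had an unadjusted p under 0.05 against 846 expected. This number was 518 against 818 expected without Nrg1 replicate 1, 793 against 838 without Vehicle replicate 4, 824 against 839 without Vehicle replicate 5, 3427 without Nrg1 replicate 2 and 3417 without Nrg1 replicate 3. With voom and sample quality weights, 28 rows passed, 3 higher and 25 lower. The lowest adjusted p with limma was 0.5682. The 5 rows with the smallest p that were higher in Nrg1 were labelled Ebf2, Insig2, Galk2, Zfp516 and Tmem147. Those labelled Ebf2, Insig2, Zfp516 and Tmem147 had 0 reads in every Vehicle library, so no fold change is given, and their Nrg1 means were 13.5 ± 13.3, 38.2 ± 56.9, 8.10 ± 4.97 and 11.3 ± 13.9 CPM (SD, n = 3). With Nrg1 replicate 1 moved by 1 row these means were 4.01 ± 3.73, 3.63 ± 3.26, 9.91 ± 6.50 and 2.45 ± 1.56 CPM. The row labelled Galk2 had a log2 fold change of 3.39 ± 0.84 (standard error). Its Vehicle mean was 0.754 CPM, under the floor of the shallow libraries, so the size of the change is not well determined. The 5 that were lower were labelled Mir1934, Myh11, Tmem40, Rps6ka2 and Ccdc61, and the log2 fold changes of the last 4 were -3.82, -2.79, -2.82 and -2.78. The Nrg1 means of these 4 rows were 2.49, 0.429, 2.62 and 0.903 CPM, under the floor of the shallow libraries, so the sizes are not well determined. The row labelled Mir1934 had 0 reads in each Nrg1 library and 3 to 8 in each Vehicle library, under or near the floor of the shallow libraries. With the library moved, the row labelled Galk2 was at 2.17, and those labelled Myh11, Tmem40, Rps6ka2 and Ccdc61 at -3.34, -1.05, 0.02 and -0.89. On the row labelled Mir1934 the moved library stood at 28.9 CPM, above every Vehicle library.

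Within the shallow libraries, 2 Nrg1 against 5 Vehicle, 3 rows passed, all lower in Nrg1. They are named here after their values were seen. The row labelled Mfsd11 (ENSMUSG00000020818) had 1 and 3 reads in Nrg1 replicates 2 and 3 and 24 to 173 in the Vehicle libraries, a difference of -4.55 ± 0.61 on the log2 scale (limma adjusted p = 0.00346). The row labelled Cpsf1 (ENSMUSG00000034022) had 24.2 ± 9.37 CPM in Nrg1 (SD, n = 2) and 337 ± 187 in Vehicle (SD, n = 5), with an adjusted p of 0.00434 from limma. The row labelled Myh11 (ENSMUSG00000018830) had 0 and 1 read in the Nrg1 libraries and 14 to 72 in Vehicle, with an adjusted p of 0.0313 from limma. In Nrg1 replicate 1, which is deep, the rows labelled Mfsd11, Cpsf1 and Myh11 stood at 99.5, 344 and 6.19 CPM as deposited, and at 11.6, 148 and 18.8 CPM after the move by 1 row. The Vehicle libraries ran from 29.1 to 229.7, from 138.7 to 600.3 and from 17.3 to 106 CPM on these rows.

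Nrg1 against Control combines diet and treatment. One row passed, the one labelled Myh11, lower in Nrg1 at 2.49 ± 3.27 CPM (SD, n = 3) than in Control at 978 ± 1390 (SD, n = 4). Control replicate 2 alone had 3057 CPM. The difference was -7.60 ± 1.00 on the log2 scale (limma adjusted p = 0.0150). There were 2199 rows with an unadjusted p under 0.05, against 846 expected, but 734 against 780 expected with Nrg1 replicate 1 moved, where 2 rows passed. Without Control replicate 3 or 4 there were 1312 or 1292. The count past the threshold was 10 without Control replicate 1, 3 without Nrg1 replicate 1, and 0 without Nrg1 replicate 2 or 3. Within the shallow libraries, 2 Nrg1 against 2 Control, 161 rows passed, 64 higher and 97 lower. The spread in that fit came mostly from the 5 Vehicle libraries, which are not compared here. Chi-square per degree of freedom was 29.1 between Control replicates 1 and 2 and at most 17.1 between Vehicle libraries. The p-values may thus understate the spread of the Control libraries. With depth class as a covariate 279 rows passed, 132 higher and 147 lower. Nrg1 replicate 1, the only deep Nrg1 library, entered that fit as deposited. With Nrg1 replicate 1 also moved, 303 passed and the balance turned, with 247 higher and 56 lower. The count and its balance thus depend on how that library is placed, and neither is read as an effect of diet or treatment. The shallow rises included the row labelled Pvalb, at 190 ± 15.4 CPM in Nrg1 and 20.52 ± 8.60 in Control (SD, n = 2 each), and that labelled Pitpnm2os1, at 298 ± 36.2 and 7.503 ± 4.78. Falls included the row labelled Tdpoz2, at 10.4 ± 8.95 and 271 ± 24.6. Both deep Control libraries lay below the shallow Nrg1 libraries on 6 of the 8 rises named by the rule, with 26.6 and 18.9 CPM on the row labelled Pvalb and 0.0986 and 0.318 on that labelled Pitpnm2os1, and not on those labelled Pcdhb6 and Btbd19. They lay above the shallow Nrg1 libraries on 5 of the 8 falls, such as the row labelled Dpcd, and not on those labelled Micu2, Dedd2 and Tdpoz2, the last at 4.53 and 11.8 CPM. On the row labelled Pitpnm2os1 the deep Nrg1 library had 0 CPM as deposited and 1.03 moved, and on that labelled Pvalb 92.3 and 139.7. After the move that library lay nearer the deep Control libraries on the first row and nearer the shallow Nrg1 libraries on the second. The counts of rises and falls thus cannot tell group from depth class. The deep class holds 2 Control libraries and 1 Nrg1 library, too few for a value of its own.

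**Figure D4:**
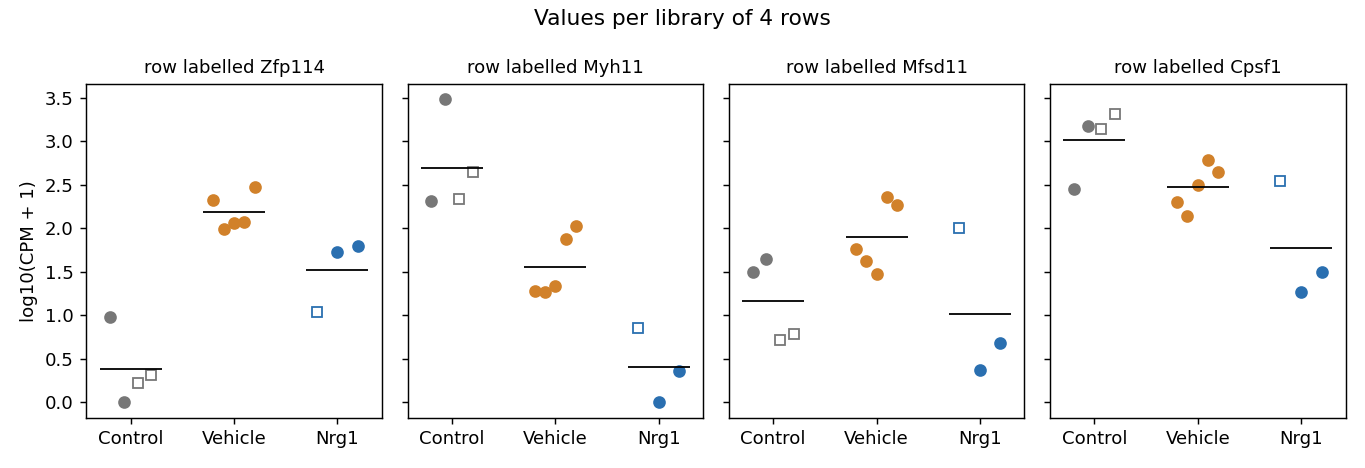
Points give log10(CPM + 1) per library for the rows labelled Zfp114, Myh11, Mfsd11 and Cpsf1, with filled circles for shallow and open squares for deep libraries and a line at each group's mean. The row labelled Zfp114 separates the 5 Vehicle libraries, none of them deep, from the 4 Control libraries. In the rows labelled Mfsd11 and Cpsf1 the deep Nrg1 library, as deposited, lies among the Vehicle libraries.

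No gene list passed in any of the 3 comparisons under camera, where 31 lists were tested. At an unadjusted p under 0.05 there were 0, 1 and 0 lists for Vehicle against Control, Nrg1 against Vehicle and Nrg1 against Control. The lowest adjusted p was 0.89 for Vehicle against Control, 0.593 for Nrg1 against Vehicle and 0.71 for Nrg1 against Control with the preset correlation, and 0.41, 0.708 and 0.987 with an estimated correlation. Fry, which asks whether a list's rows move one way, gave 0.485, 0.566 and 0.27. Its mixed test, which asks whether rows change in either direction, called 0, 0 and 1 list. The 1 list, in Nrg1 against Control, was the endothelial and mural labels, with an adjusted p of 1.67e-05 from fry in limma. It rested on the member labelled Myh11, without which the unadjusted mixed p of the list was 0.186. For the 20 tested labels of disease-associated microglia the median log2 fold change was -0.048 in Vehicle against Control and -0.773 in Nrg1 against Vehicle. For the 10 homeostatic labels it was 0.049 and 0.251, and for the 9 oligodendrocyte labels it was -0.067 and -0.362. The sign of the median and the direction of the camera test differed for 12 lists in Vehicle against Control, including the disease-associated and oligodendrocyte labels, and for 7 and 6 lists in the other comparisons. Adjusted over the list alone, and counting a label once per list, 3, 4 and 10 members passed in the 3 comparisons, and over all rows tested 0, 0 and 1. Because labels and levels did not match, these lists are sets of rows here rather than sets of genes.

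The log2 fold changes of Vehicle against Control and Nrg1 against Vehicle had a Pearson correlation of -0.385 across 16925 rows, which are not independent replicates. The Vehicle libraries enter both with opposite sign. With no effect and equal spread in every group, 100 simulations gave a mean of -0.408, from -0.427 to -0.388. The covariance was -0.559 against a simulated -0.394. With the Vehicle libraries split so that each comparison had its own, the median over 20 splits was -0.28. Within the shallow libraries the correlation was -0.025 against a simulated mean of -0.285, with a covariance of -0.0167 against -0.145. With Nrg1 replicate 1 moved it was -0.659, without Nrg1 replicate 1 it was -0.035, and with depth class as a covariate it turned to 0.216. Deep libraries are in the Control and Nrg1 groups and not in Vehicle. A difference between deep and shallow libraries can thus enter both comparisons with opposite sign, and the simulations held no depth classes. The negative values are not read as neuregulin moving rows back towards Control.

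Vehicle against Control and Nrg1 against Control share the Control libraries, and their fold changes correlated at 0.505 against a simulated mean of 0.488, from 0.474 to 0.507. The covariance was 0.783 against a simulated 0.4926. A difference between deep and shallow libraries can also enter both comparisons through the deep Control libraries, and the simulations held none. With the Control libraries split, the 6 values had a median of 0.383 and ran from -0.288 to 0.42. Within the shallow libraries the correlation was 0.729 against a simulated mean of 0.598, with a covariance of 0.705 against 0.363. Over all libraries it was 0.831 without Nrg1 replicate 1, 0.267 without Nrg1 replicate 2 and 0.265 without Nrg1 replicate 3. In the shallow libraries, 27 rows were higher and 20 lower than Control in both comparisons, where independent lists of those sizes would share 0.166 and 0.151 rows among 15428. In 100 simulations of unchanged groups with equal spread, a mean of 0.01 to 0.03 rows was called per direction and comparison. These groups shared the Control libraries, and a mean of 0.01 rows per direction was called in both comparisons. The simulation thus gives no overlap for lists of the observed sizes. The product of list sizes leaves out the shared Control libraries. With 2 shallow Control libraries no further split was made, and part of the overlap may come from their sharing.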

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

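All tests of explanations in this part were chosen after the results they bear on had been seen. Across 32 groups of values, 3 had a library far from the rest of its group by Dixon's criterion. About 1 in 20 groups is set apart by chance alone, or 1.6 here. That number is somewhat too high, since the Vehicle values of the rows labelled Ebf2, Insig2, Zfp516 and Tmem147 were all 0 and could not be flagged. The 3 groups flagged are of rows that had been named from these same data. On the row labelled Zfp114, Control replicate 1 stood at 8.46 CPM and the next Control library at 1.06. On the row labelled Mir1934, Vehicle replicate 5 stood at 4.42 CPM and the next Vehicle library at 9.01, which is a difference between 3 and 7 reads. On the row labelled Myh11, Control replicate 2 stood at 3057 CPM and the next Control library at 438.5.

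Rows labelled with genes that the sorted cells express lay at the floor. Too few reads cannot be the whole reason, since all 7 genes checked lay under 10 CPM in both deep Control libraries. Cells of another type in the sort cannot be the whole reason either, since any cell type would hold the ribosomal protein labels near the top. Their median percentile was 55.7. Whether other cells were present cannot be told from labels that do not carry the levels of their genes. A candidate explanation is that the values stand in another row order than the labels: over 100 stretches of rows, the share at the floor or without values followed the share of small RNA genes along sorted Ensembl numbers of GENCODE M21 with a correlation of 0.533, matched by 3 of 99 circular shifts, the best of which was 1 stretch away at 0.685. Stretches 88 to 97 went against it, with 60.8% to 73.6% of rows at the floor or without values and 0% small RNA genes. Neighbouring stretches are alike, so the shifts are not independent and the share of them is weak evidence. No explanation from the study's groups was tested, and no row was renamed.

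Nrg1 replicate 1 stood apart from every other library. Low depth is argued against by its 5808854 reads, the most of the 12, and an effect of neuregulin by Nrg1 replicates 2 and 3, whose lowest rho with a Vehicle library was 0.82. A displacement of its values by 1 row may account for it, since moving them by 1 row gave a rho of 0.903 with Control replicate 3, and no other move within 5 rows gave more than 0.276 with that library. The move was found on these data and is a hypothesis.

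The 3 deep libraries stood apart from the 9 shallow ones. When the deep Control libraries were thinned to 666845 reads, their highest rho with a shallow library was 0.71, under the lowest of 0.79 among shallow pairs, which argues against depth alone. The study's groups are argued against by the deep Control libraries, whose rho with the moved Nrg1 replicate 1 was at least 0.885 and with shallow Control libraries at most 0.705. Whether the deep libraries were made or processed apart stays open: the lowest rho among them, 0.885, restates the pattern, and the labels name no batch.

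Other splits of the libraries were counted for each comparison. For Vehicle against Control, 2 of 100 splits, the real one included, gave as many as the 1 row of the real grouping, and the highest other gave 25 rows. Chance is not firmly excluded by that share, since the splits treat deep and shallow libraries as alike and the row missed the threshold without Control replicate 2. That split put Control replicates 3 and 4 with Vehicle replicates 1, 2 and 3, so it follows the deep libraries in part, and points to a structure of the samples larger than the groups. Within the shallow libraries the real grouping gave 64 rows. For Nrg1 against Vehicle the real count was 0, which all 56 splits meet by construction, so the splits say nothing on chance, and the highest other gave 12 rows. For Nrg1 against Control, 3 of 35 splits gave at least the real 1 row, so chance is not excluded there. The highest other gave 6058 rows and put the 3 deep libraries together, and within the shallow libraries the real grouping gave 161 rows.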

How the results depend on the processing

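The settings named below with the shallow libraries, depth class, the moved library, a pseudocount of 4 and rescaling to equal sums were chosen after seeing the data. Where no reason is stated, the cause was not tested.

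For Vehicle against Control the 1 row became 2 with only the groups compared, 2 with depth class as covariate, 3254 with the oligodendrocyte marker rows as covariate, 64 in the shallow libraries, and 18 with Nrg1 replicate 1 moved and depth class as covariate. Leaving out libraries gave 0 to 14 rows, with 0 without Control replicate 2 and 14 without Nrg1 replicate 1. For Nrg1 against Vehicle the 0 rows became 28 with voom weights, where Nrg1 replicate 1 weighed 0.0563, and 3 in the shallow libraries. Leaving out any library gave 0 to 0. For Nrg1 against Control the 1 row became 0 without a filter, 0 with only the groups compared, 0 with a pseudocount of 4, 4 after rescaling, 55 with voom weights, 161 in the shallow libraries, 279 with depth class, 2 with the moved library and 303 with both. Leaving out libraries gave 0 to 10 rows, with 10 without Control replicate 1, 3 without Nrg1 replicate 1, and 0 without Nrg1 replicate 2 or 3. Apart from the replicate number, given separately, the remaining settings kept these counts within 1.5 times. Under camera or directional fry, all 26 settings left 0 lists past the threshold in each comparison, leave-one-out from 0 to 0 included.

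The correlation of Vehicle-vs-Control with Nrg1-vs-Vehicle changes was -0.28 with split Vehicle libraries, -0.025 in the shallow libraries, 0.216 with depth class, -0.659 with the moved library and -0.236 with both. It ran from -0.409 to -0.035 with libraries left out, the last without Nrg1 replicate 1. That of Vehicle-vs-Control with Nrg1-vs-Control changes was 0.729 in the shallow libraries and 0.791 with depth class. It ran from 0.265 to 0.831 with libraries left out, with 0.831 without Nrg1 replicate 1, 0.267 without Nrg1 replicate 2 and 0.265 without Nrg1 replicate 3. Restricting these to rows past the threshold in Vehicle against Control gave no value, as 1 row passed.

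The replicate number of the titles was tried as a term, the replicate block. It gave 0 rows in each of the 3 comparisons, 0 lists, and correlations of -0.471 and 0.436. Of 10 same-numbered pairs, 1 had deviations correlated above 0.1, and the values ran from -0.343 to 0.279. The 37 pairs with different numbers ran from -0.385 to 0.422, with 9 above 0.1. These deviations also carry the split into deep and shallow libraries, so they cannot decide whether same-numbered libraries are paired. The lost calls are not read either way.

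The row labelled Zfp114 kept its direction in Vehicle against Control, at 5.56 to 6.65 with libraries left out. It missed the threshold without Control replicate 2 (limma adjusted p = 0.0503), where the range over left-out libraries was 0.00031 to 0.0503. The row labelled Myh11 in Nrg1 against Control kept its direction, at -8.35 to -6.72, and passed in 10 of 12 such settings. Of the rows given as values only, that labelled Rps6ka2 changed sign, to 0.02, with the moved library, since another row's value takes its place. Depth limits the rows at few reads: where a group holds 3 reads or fewer, up to 6.19 CPM in the shallow libraries, the size of a change is not well determined.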

Other observations

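The values in this part were picked after the data were seen and no test was run on them, and no cell type or pathway is read from row labels. Among shallow libraries, Vehicle replicates 1, 2 and 3 had rho of 0.884 to 0.895 with one another and 0.851 to 0.854 with Vehicle replicates 4 and 5, which had 0.87 between them. The chi-square per degree of freedom of read counts was 3.89 to 6.63 within the first 3, 5.92 between the other pair, and 10.4 to 17.1 across. Control replicates 1 and 2 differed more, at 29.1, and Control replicate 2 had the highest share of reads on its 10 highest rows, at 25.3%. The 3 rows lower in Nrg1 than in Vehicle among shallow libraries were also higher in Vehicle replicates 4 and 5 than in replicates 1, 2 and 3, with 173 and 125 reads against 24 to 44 on the row labelled Mfsd11.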
